A study of Homo sapiens with 8 samples.

How the data were processed

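Single-cell RNA sequencing by Drop-seq, which captures the polyadenylated RNA of single cells on barcoded beads in droplets, was done in 8 batches of K562 cells, a human leukaemia line that makes embryonic and fetal globins. The cells expressed dCas9-KRAB, a catalytically dead Cas9 fused to a repressor domain, and were infected with a lentiviral pool of 10 sgRNAs. Each sgRNA is read out through a barcode of 12 bases in its own construct. All 8 batches belong to 1 group, so every comparison was made between barcodes with different sgRNAs inside the batches. The bulk libraries, the separately infected cells and the larger sgRNA library that the series description mentions were not analysed here.

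The deposited files hold raw counts per RefSeq transcript and cell barcode, which the authors made with Picard and featureCounts 1.5.0 on genome build hg19. The version of Picard, the aligner, the quality filters, the collapsing of molecular identifiers and the way sgRNA barcodes were assigned to cell barcodes are not given in the sources used here. Counts are therefore called counts and not molecules, and intervals cover counting error only. A further deposited matrix holds the counts of 69 of the cell barcodes, and the columns of all 69 equal those of the batch files. How the 69 were chosen is not given in the sources used here. For each cell barcode, the authors also list the sgRNA barcodes detected and the reads of each.

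The 51097 transcripts of the files carry 26538 gene symbols. A read is counted in every transcript it overlaps, so a gene's count in a barcode was the highest count among its transcripts. The lentiviral construct, which is listed among the transcripts and holds 0.132% as many counts as the genes, was kept out of the gene counts. The sgRNA sequences were searched in the transcripts of a GRCh38 annotation, with no genome sequence at hand.

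Counts of barcodes with exactly one detected sgRNA were summed per batch and sgRNA into pseudobulks of at least 3 barcodes. This gave 49 pseudobulks from 325 barcodes, with 8941 to 1575810 counts each and a median of 91126. They were fitted in edgeR 4.0.16 on R 4.3.3, with TMM scaling, filterByExpr with the sgRNA as group, batch and sgRNA as terms, robust dispersions and the quasi-likelihood F-test, which left 9075 genes. Since sgRNA60 had 1 pseudobulk, the filter was weak. The common dispersion was 2.90. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The reference was sgRNA63, aimed at an HSBP1 enhancer outside the beta-globin locus, the only HSBP1 sgRNA with enough barcodes in at least 3 batches. An element's effect was the mean of the coefficients of its sgRNAs minus that of sgRNA63. This design, the gene lists, the rule for named genes and most alternatives were set before the data were examined.

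HBG1 and HBG2, whose reads can be shared, were also summed. The log2 ratio of their CPM, counts scaled to a fixed library total, to the reference was taken within each batch, with 0.5 counts added, and tested with a two-sided exact sign-flip permutation test over batches. Elements were compared with each other in the same edgeR fit, adjusted over the 3 pairs of elements for each gene. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over 39 tests of 13 lists in 3 contrasts. The mitochondrially encoded list had 0 of its 15 genes in the matrix, and the megakaryocyte list and the leukocyte and fibroblast list were used as shares of counts. Whether sgRNAs were spread alike over batches was tested by permuting the labels over all barcodes, because a permutation within batches would leave the statistic unchanged.

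The genes named are all measured globin genes, HSBP1 and HSPB1, up to 10 genes with the smallest p among those past the threshold in each direction, up to 5 more where fewer than 5 passed, and for each list 2 to 4 members with the smallest p in the contrast where the list had its smallest p. The values of 2 list members that this rule names are not reported here.

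After the data had been seen, a second version was added. It used the barcodes of the authors' final matrix in which 1 sgRNA held at least 80% of the sgRNA reads, pseudobulks of at least 1 barcode, and all HSBP1 sgRNAs pooled as reference. It has 30 pseudobulks from 55 barcodes, with 52852 to 1546440 counts each, 8959 tested genes and a common dispersion of 1.79. Batch values of 4 measures in it, as log2 of CPM plus 10, were compared with the reference in 12 two-sided exact permutation tests. The alternatives set in advance were DESeq2 1.42.0, other scalings, filters, references and barcode minimums, all barcodes carrying an sgRNA, thinned barcodes, and leaving out each batch. Apart from the left-out batches, 17 such settings were tried and 10 more were added after the data had been seen. Barcodes with several sgRNAs were left out of the fit set in advance, because more of the barcodes with any sgRNA carried exactly one.

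No doublet caller was run, and the sources used here name no removal of doublets. A barcode with several sgRNAs can be a cell infected more than once or a droplet with several cells, which the counts do not separate. Such barcodes were 28 of the 69 of the final matrix (40.6%) and 133 of the 431 others with an sgRNA (30.9%). In the final matrix their median was 145082 counts, against 150515 with exactly one sgRNA. Of the 55 barcodes used in the second version, 14 carried several sgRNAs. Doublets of cells with the same sgRNA, or with a cell without one, remain in every version.

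The fit was tested on simulated counts with the same layout. The changed genes were drawn only from those above a set CPM level, so the shares below do not cover genes with lower counts. At a dispersion of 0.1 it called between 98% and 100% of genes raised or lowered by 2 or 4 on the log2 scale. At the dispersion estimated from the data it called 2% of genes lowered by 4 on this scale and 0% of those with the other changes, while 70% of the former had an unadjusted p under 0.05. In the layout of the final matrix, 0% of genes lowered by 4 were called and 64% of them had an unadjusted p under 0.05.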

Results

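The data are counts of 981 cell barcodes from 8 Drop-seq batches of K562 cells that express dCas9-KRAB and carry sgRNAs aimed at the beta-globin locus, whose genes K562 cells transcribe, or at HSBP1 on another chromosome. Batches 1 to 8 held 87, 75, 147, 167, 107, 92, 157 and 149 barcodes. Their total counts were 3822997, 3167941, 2144095, 1322795, 1012707, 6100927, 2036807 and 2999629 in the same order, 22607898 in all. The median barcode held 4714 counts, with a range from 1036 to 1208335, and the batch medians ran from 1773 in batch 5 to 10166.5 in batch 6. No sgRNA was listed for 481 barcodes (49.0%), exactly one for 339 (34.6%) and several for 161 (16.4%).

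The 10 sgRNAs fall on 5 elements. HS2, the erythroid enhancer of the beta-globin locus control region, is the target of sgRNA44 and sgRNA46, the HBG1 and HBG2 promoters of sgRNA56 and sgRNA57, and the HBE1 promoter of sgRNA80 and sgRNA82. The promoter of HSBP1, which encodes a heat shock factor binding protein, is the target of sgRNA59 and sgRNA60, and an HSBP1 enhancer that of sgRNA62 and sgRNA63. Among single-sgRNA barcodes, 69 were assigned to HS2, 133 to the HBG1/2 promoter, 104 to the HBE1 promoter, 10 to the HSBP1 promoter and 23 to the HSBP1 enhancer. The most frequent sgRNA was sgRNA56 with 91 of 339 barcodes (26.8%, exact binomial 95% interval 22.2 to 31.9%), and the reference sgRNA63 had 22 (6.49%, 4.11 to 9.66%). The makeup did not differ detectably between batches (chi-square 59.2, 63 degrees of freedom, permutation p = 0.627). In GRCh38 transcripts, sgRNA56 matched chromosome 11 from 5254915 to 5254934, 134 bases upstream of HBG2, and sgRNA57 matched 5254889 to 5254908, 108 bases upstream. A site upstream of HBG1 would be missed where no searched transcript covers it. The search therefore does not show that these sgRNAs match at HBG2 alone. The site of sgRNA63 lies on chromosome 16 from 83813905 to 83813923, in the UTR in exon 4 of an HSBP1 transcript. The sequences of sgRNA44, sgRNA46, sgRNA80 and sgRNA82 had no match in the transcripts searched.

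The authors' final matrix keeps 69 barcodes, which hold 74.7% of all counts. Their median was 145479 counts and 5594 detected genes, against 4416.5 counts and 444 genes in the other barcodes. Exactly one sgRNA was listed for 41 of them and several for 28, and in 55 a single sgRNA held at least 80% of the sgRNA reads. The single-sgRNA barcodes among them hold 79.5% of the counts of all single-sgRNA barcodes, so pseudobulk values rest mainly on these few barcodes. The median was 39 sgRNA reads in the final matrix and 2 in the single-sgRNA barcodes outside it. Assignments outside it thus rest on few reads, and their error was not tested.

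Globin RNA in these cells was mainly embryonic and fetal. Over all barcodes, HBE1, the embryonic epsilon globin, had 22865 counts in 395 barcodes, and the fetal gamma globins HBG2 and HBG1 had 12221 and 7261 counts in 676 and 530 barcodes. Single final-matrix barcodes, both with sgRNA56, held 7505 and 6370 of the HBE1 counts, so the HBE1 total rests largely on few barcodes. HBD, the minor adult delta globin, had 3713 counts in 180 barcodes, and HBB, the adult beta globin, had 8 counts in 7 barcodes. From the alpha-globin locus, the embryonic HBZ had 8522 counts, HBA1 had 3943, HBA2 had 2160, HBQ1 had 141 and HBM had 7. HBB, HBM and HBQ1 had too few counts for the fit of single-sgRNA barcodes. In hg19 on chromosome 11, HBE1 (NM_005330) lies from 5289580 to 5291373, HBG2 (NM_000184) from 5274421 to 5276011, HBG1 (NM_000559) from 5269502 to 5271087 and HBD (NM_000519) from 5254059 to 5255858. HSBP1 was measured at 152.6 CPM over all barcodes.

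With sgRNAs on the HBG1/2 promoter, the summed counts of the targeted genes HBG1 and HBG2 were 290 ± 177 CPM (SD, n = 8 batches), against 1262 ± 1289 CPM (n = 4 batches) with the reference sgRNA63. The ratio within batches was a log2 of −2.62 (SD 1.15) and lay below 0 in 4 of 4 batches. A two-sided exact sign-flip test gave p = 0.125, the smallest p that 4 batches allow, so it could not pass (adjusted p = 0.188). Without the 5% of barcodes with most counts the ratio was −1.13 (SD 0.72, n = 3 batches). In the edgeR fit, HBG1 was at −1.73 (SE 1.03) and HBG2 at −1.58 (SE 0.93) in 15 pseudobulks against 4, both 0.239 when adjusted over the list alone. Without the 5% of barcodes with most counts they were at −0.045 and −0.66, and with each barcode thinned to 1000 counts at −0.39 and −0.61. HBD was at 2.53 (SE 1.89) and HBE1 at 0.86 (SE 1.53), with neither past the threshold. HBE1 turned to −0.49 without batch 8, and without batch 4 HBE1 was at 5.52 and HBD at 6.71, each with 0.0189 adjusted over the list alone.

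Across all genes, edgeR called 0 for the HBG1/2 promoter, with 673 genes at an unadjusted p under 0.05 and 234 called by DESeq2. DESeq2 was not run with redrawn sgRNA labels, here or below, so how many of its calls arise by chance is not known. None of the genes with the smallest p passed in edgeR. PSEN2, a presenilin, was at −7.07 (adjusted p = 0.318). PDSS1 was at −6.21, SCAMP1 at −6.48, PDE3B at −7.10 and ADO at −6.65 (each 0.398). Of these genes DESeq2 called PDE3B (−20.9, adjusted p = 0.000425) and ADO (−22.2, 0.0103). HSBP1 was at −1.33 (SE 1.20) and HSPB1, a small heat shock protein, at 0.084 (SE 1.40).

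With sgRNAs on HS2, HBE1 stood at 88.4 ± 111 CPM (SD, n = 8 batches) and the sum of HBG1 and HBG2 at 505 ± 506 CPM, against 834 ± 1641 and 1262 ± 1289 CPM with sgRNA63 (n = 4 batches). The median of HBE1 over batches was 18.3 CPM with HS2 sgRNAs and 19.5 CPM with sgRNA63. The fitted log2 fold changes were −3.29 (SE 1.56) for HBE1, −2.32 (SE 1.08) for HBG1 and −1.98 (SE 0.98) for HBG2, with unadjusted p of 0.0382, 0.0337 and 0.0452. Each was 0.0753 in edgeR when adjusted over the list alone, so none passed. Without the 5% of barcodes with most counts HBE1, HBG1 and HBG2 were at −0.27, −0.81 and −0.91, and with each barcode thinned to 1000 counts at −2.14, −0.083 and −0.71. With at least 5 barcodes per pseudobulk HBE1 turned to 3.06. HBD was at −0.65 (SE 1.98). DESeq2 put these 3 genes at −3.23, −2.31 and −2.05, each with 0.00764 adjusted over the list alone. Over 19 alternatives the list-adjusted p of HBE1 ran from 2.39e-05 to 0.900. Without batch 7, HBE1 (−4.73) and HBG2 (−3.05) reached 0.00613 and HBG1 (−2.73) reached 0.0356, while without batch 4 HBE1 was at 1.43 and HBD at 3.82. The ratio of the HBG1 and HBG2 sum within batches was −1.48 (SD 2.81), below 0 in 2 of 4 batches (two-sided exact p = 0.5).

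Across all genes, edgeR called 0 for HS2, with 828 at an unadjusted p under 0.05 and 310 called by DESeq2. Without batch 5 it called 2. The smallest p belonged to C10orf88 (−9.10) and ANXA4 (−8.35), an annexin, both with an adjusted p of 0.0749 in edgeR. PDSS1 (−6.92), ABHD11 (−7.60) and PITPNA (−6.26) followed. DESeq2 called these genes except ANXA4. It gave C10orf88 −20.5 (adjusted p = 0.0234), PDSS1 −5.99 (0.0136), ABHD11 −14.5 (9.17e-07) and PITPNA −16.9 (0.00126). HSBP1 was at −2.43 (SE 1.19) and HSPB1 at 0.18 (SE 1.44).

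With sgRNAs on the HBE1 promoter, the targeted gene HBE1 was at 182 ± 247 CPM (SD, n = 8 batches), against 834 ± 1641 CPM with sgRNA63 (n = 4 batches), with medians of 93.4 and 19.5 CPM. Its log2 fold change in the edgeR fit was −1.44 (SE 1.38) and did not pass. It turned to 5.30 with at least 5 barcodes per pseudobulk and to 0.96 without the 5% of barcodes with most counts. The sum of HBG1 and HBG2 was 2026 ± 1148 CPM, and its ratio within batches was 0.97 (SD 0.67), above 0 in 4 of 4 batches (two-sided exact p = 0.125, the smallest possible). The fit put HBG2 at 0.17 (SE 0.98), HBG1 at −0.059 (SE 1.08) and HBD at −0.40 (SE 1.79). Without batch 4 HBE1 turned to 2.74, HBG1 to 0.44 and HBD to 3.80. Without batch 5 HBG2 turned to −0.11.

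For the HBE1 promoter, edgeR called 1 gene across all genes, with 620 at an unadjusted p under 0.05 and 246 called by DESeq2. SCAMP1, which encodes a carrier membrane protein of secretory vesicles, fell by 9.06 on the log2 scale (SE 1.84, adjusted p = 0.0400). It was not called by DESeq2 (0.252), and the call was lost without each of batches 2 to 7. The next genes did not pass in edgeR. ACO1, the cytosolic aconitase that also binds iron-responsive elements, was at −6.05 (adjusted p = 0.307). ZNF44 was at −5.17, OBFC1 at −6.06, PDE3B at −6.41 and TOB1 at −5.59 (each 0.682). Of these genes DESeq2 called ACO1 (−18.6, adjusted p = 0.000274) and OBFC1 (−19.6, 0.0360). HSBP1 was at −1.90 (SE 1.23) and HSPB1 at −0.66 (SE 1.40).

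The alpha-globin locus on chromosome 16 serves as a comparison outside the targeted locus. Its genes did not pass in any of the 3 contrasts. HBZ was at 0.60 (SE 1.06), 0.91 (SE 1.09) and 0.76 (SE 1.06) for HS2, the HBG1/2 promoter and the HBE1 promoter. HBA2 was at 0.61, 1.49 and 0.96, and HBA1 at 0.77, 0.73 and 0.68. The pseudogene HBBP1, in the beta-globin locus, was at 1.44, 2.54 and 0.94. HSBP1, the target of the reference sgRNA, was at 336 ± 284 CPM with sgRNA63 (SD, n = 4 batches), and at 78.8 ± 52.0 CPM with HS2, 147 ± 66.7 CPM with HBG1/2 promoter and 109 ± 56.4 CPM with HBE1 promoter sgRNAs (n = 8 batches each), so it was not lower where it was targeted.

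The elements differed from each other in globin expression in single-sgRNA barcodes. These differences were not refitted with thinned barcodes or without the barcodes with most counts. Several values against sgRNA63 shrank in those settings. How far the differences rest on a few deep barcodes was therefore not tested in this way. HBE1 was lower with HS2 sgRNAs than with HBG1/2 promoter sgRNAs (log2 difference −4.15, SE 1.06, adjusted p = 0.000531 over the 3 pairs in edgeR), and so was HBD (−3.18, SE 1.16, 0.0107). Against HBE1 promoter sgRNAs, HBG1/2 promoter sgRNAs left HBG2 lower (−1.74, SE 0.62, 0.00884), HBG1 lower (−1.67, SE 0.71, 0.0322), HBE1 higher (2.30, SE 0.86, 0.0133) and HBD higher (2.93, SE 0.97, 0.00982). HS2 sgRNAs left HBG2 lower (−2.14, SE 0.72, 0.00884) and HBG1 lower (−2.26, SE 0.81, 0.0193) than HBE1 promoter sgRNAs. HBG1 and HBG2 did not differ detectably between HS2 and the HBG1/2 promoter (−0.59, SE 0.78, and −0.40, SE 0.69). HBE1 between HS2 and its own promoter (−1.85, SE 0.95) had an adjusted p of 0.0548, passing without batch 3 (−2.44) and batch 7 (−2.80).

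Batch 8 mattered in 5 of these differences: without it HBG2 was at −1.82 for HS2 and −1.72 for the HBG1/2 promoter (each 0.0572), HBG1 at −2.01 and −1.80 (each 0.0624), all against the HBE1 promoter, and HBE1 at 1.64 (0.104). HBE1 of the HBG1/2 promoter against the HBE1 promoter also missed without batch 6 (1.79, 0.0837). HBG1 of HS2 missed without batch 1 (−2.06) or 6 (−2.23), and HBG1 of the HBG1/2 promoter without batch 1 (−1.57), 2 (−1.57), 5 (−1.51) or 6 (−1.64). With at least 5 barcodes per pseudobulk none of the 8 differences passed, with adjusted p from 0.109 to 0.277, and with library size alone as the scaling HBD of HS2 against the HBG1/2 promoter missed (−2.59, 0.0538). The sum of HBG1 and HBG2, taken against all barcodes with sgRNAs of other elements, was lower with HBG1/2 promoter sgRNAs in 8 of 8 batches (log2 −2.19, SD 1.41, two-sided exact p = 0.00781, the smallest possible, adjusted p = 0.0117) and higher with HBE1 promoter sgRNAs in 8 of 8 (2.41, the same p). The 235 barcodes of the latter reference include 133 with HBG1/2 promoter and 69 with HS2 sgRNAs, where the sum is low. Against barcodes with no sgRNA the HBE1 promoter was at 1.20 (SD 0.70, higher in 8 of 8, exact p = 0.00781, adjusted p = 0.0117). Of these 481 barcodes 241 held counts of the lentiviral construct, so this reference may include infected cells. With all barcodes carrying the sgRNA, against sgRNA63, the HBE1 promoter was at −0.070 (SD 0.92, lower in 4 of 8, exact p = 0.852, adjusted p = 0.852). The HBG1/2 promoter was at −1.75 and −2.04 in these comparisons, lower in 8 of 8 in each.

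Between the 2 sgRNAs of an element, no globin gene differed past the threshold. HBG1 was at −1.85 (SE 1.00) for sgRNA80 minus sgRNA82 with an adjusted p of 0.201 in edgeR, HBG2 at −1.44 (0.296), HBE1 at 1.36 (SE 1.35) for sgRNA44 minus sgRNA46, and HBG2 at −0.49 for sgRNA56 minus sgRNA57. Over all genes edgeR called 0 in each of the 3 pairs, with 856, 967 and 1089 at an unadjusted p under 0.05. For pair 56 and 57 it called 1 without batch 7. DESeq2 was not run for these pairs. Against sgRNA63, edgeR called 0 genes for each of sgRNA44, sgRNA46, sgRNA56, sgRNA57, sgRNA80 and sgRNA82, with 617, 867, 538, 808, 845 and 583 at an unadjusted p under 0.05 and 230, 402, 197, 292, 339 and 221 called by DESeq2.

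When every barcode carrying an sgRNA was used, whatever else it carried, sgRNA63 gained 8 pseudobulks in place of 4. With HS2 sgRNAs 4 globin genes fell: HBE1 to a log2 fold change of −3.80 (SE 0.75, 2.39e-05 in edgeR when adjusted over the list alone), HBG2 to −2.28 (SE 0.47, 2.86e-05), HBG1 to −2.29 (SE 0.53, 9.90e-05) and HBD to −2.26 (SE 0.84, 0.0116). With HBG1/2 promoter sgRNAs, HBG2 fell to −1.77 (SE 0.47, 0.00171) and HBG1 to −1.81 (SE 0.52, 0.00266), while HBD was at 1.67 (0.0973) and did not pass. HBE1 was at −1.94 (SE 0.77, 0.0724) with HBE1 promoter sgRNAs. Over the alternatives tried, the list-adjusted p of HBG2 ran from 2.86e-05 to 0.900 for HS2 and from 0.000239 to 0.856 for the HBG1/2 promoter. Over all genes edgeR called 0 for each element, with 899, 777 and 860 at an unadjusted p under 0.05; DESeq2 was not run here. HBQ1, left out of the single-sgRNA and final-matrix fits, was at −1.03, 0.15 and −0.21 for HS2, the HBG1/2 promoter and the HBE1 promoter and did not pass. A barcode with several sgRNAs enters several pseudobulks here, which are therefore not independent.

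**Figure D1:**
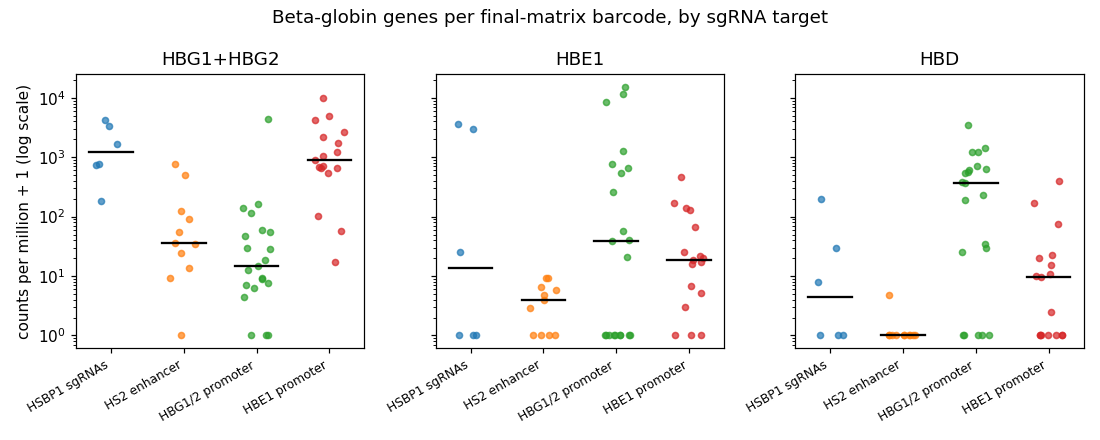
CPM plus 1, on a log axis, of HBG1+HBG2, HBE1 and HBD in each final-matrix barcode with a dominant sgRNA, grouped by targeted element, with a black line at the median. The HBG1+HBG2 median is 13.9 CPM with HBG1/2 promoter sgRNAs and 34.7 with HS2 sgRNAs, against 882 with HBE1 promoter and 1211 with HSBP1 sgRNAs.

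In the barcodes of the final matrix, taken up after the data had been seen, the globin genes stood further apart. The sum of HBG1 and HBG2 was 73.5 ± 91.7 CPM (SD, n = 8 batches) with HBG1/2 promoter sgRNAs and 148 ± 111 CPM (n = 5) with HS2 sgRNAs, against 2224 ± 1379 CPM (n = 5) with HBE1 promoter sgRNAs and 1963 ± 1743 CPM (n = 5) with the pooled HSBP1 sgRNAs. It lay under 100 CPM in 17 of 21 HBG1/2 promoter barcodes and 8 of 11 HS2 barcodes, and in 2 of 17 HBE1 promoter and 0 of 6 HSBP1 barcodes. HBE1 was at 2.58 ± 2.46 CPM with HS2 sgRNAs and 59.9 ± 84.3 CPM with HBE1 promoter sgRNAs, against 1930 ± 3393 CPM with HBG1/2 promoter sgRNAs and 1325 ± 1824 CPM with HSBP1 sgRNAs. The HBE1 medians over batches were 3.60, 18.2, 170 and 10.6 CPM in the same order, and of the 6 HSBP1 barcodes 2 held over 1000 CPM and 3 held 0. HBD reached 497 ± 221 CPM with HBG1/2 promoter sgRNAs, against 47.0 ± 86.2 CPM with HSBP1 sgRNAs, 46.6 ± 51.8 CPM with HBE1 promoter sgRNAs and 0.256 ± 0.572 CPM with HS2 sgRNAs, which had 1 HBD count.

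For HBG1/2 promoter sgRNAs in these barcodes, HBG1 fell to a log2 fold change of −6.06 (SE 1.28) and HBG2 to −4.69 (SE 1.06), with 0.000194 and 0.000239 in edgeR when adjusted over the list alone. These were the 2 smallest p of all genes in that contrast. HBD rose to 4.43 (SE 1.35, 0.00423), and HBE1 was at 0.40 (SE 1.32). For HS2 sgRNAs, HBG2 fell to −4.11 (SE 0.94, 0.000596), HBG1 to −3.81 (SE 1.01, 0.00165), HBE1 to −7.53 (SE 2.11, 0.00269) and HBD to −5.02 (SE 1.58, 0.00426), the last from a single count, so its size depends on the fit. For HBE1 promoter sgRNAs, HBE1 was at −5.13 (SE 1.93, 0.0691), passing without batch 8 (−6.19, 0.0395), and HBG2 at −0.73. The HBE1 and HBD calls of HS2 were lost without batch 6 (−3.69, 0.257, and −4.01, 0.100), that of HBE1 also with exactly one sgRNA per barcode (−5.54, 0.161), and that of HBD for the HBG1/2 promoter with all barcodes carrying the sgRNA (2.70, 0.0566). Over 7 refits of this version the list-adjusted p of HBG2 ran from 9.40e-06 to 0.000591 for HS2 and from 1.01e-07 to 0.00781 for the HBG1/2 promoter. Over all genes edgeR called 0 for each element, with 531, 468 and 440 at an unadjusted p under 0.05 for HS2, the HBG1/2 promoter and the HBE1 promoter and 536, 584 and 522 called by DESeq2. DESeq2 thus called more genes after adjustment than edgeR had at an unadjusted p under 0.05. Its calls were not checked against chance and are not taken as changed genes. For sgRNA56 alone edgeR called 1, HBG2, which fell to −5.74 (SE 0.97, adjusted p = 0.0110 over all genes).

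A comparison of batch values, with n = 8 against 5 batches, gave a log2 difference of −4.68 for the sum of HBG1 and HBG2 with HBG1/2 promoter sgRNAs (two-sided exact permutation p = 0.00233, adjusted p = 0.0280 over 12 tests), and the sum was lower in 5 of 5 shared batches. This test does not pair the batches. Within the 5 shared batches the ratio was −5.64 (SD 2.31), and an exact sign-flip test gave p = 0.0625, the smallest p that 5 batches allow, so it could not pass (adjusted p = 0.188). Within 8 batches, against final-matrix barcodes with sgRNAs of other elements, it was −4.86 (SD 2.02, lower in 8 of 8, exact p = 0.00781, adjusted p = 0.0234). In the unpaired test with HS2 sgRNAs the difference was −3.30 (exact p = 0.0238, adjusted 0.0952), lower in 3 of 3 shared batches. For HBD with HBG1/2 promoter sgRNAs it was 3.69 (exact p = 0.0109, adjusted 0.0653), higher in 5 of 5 shared batches. With HS2 sgRNAs, HBE1 was at −3.25 (exact p = 0.238, adjusted 0.476) and HBD at −1.38 (exact p = 0.167, adjusted 0.400), each lower in 2 of 3 shared batches, so the edgeR calls of these genes did not hold in this test. HBE1 with HBE1 promoter sgRNAs was at −1.56 (exact p = 0.476, adjusted 0.610). The other 6 tests had adjusted p from 0.400 to 0.721, so 1 of the 12 passed the threshold.

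**Figure D2:**
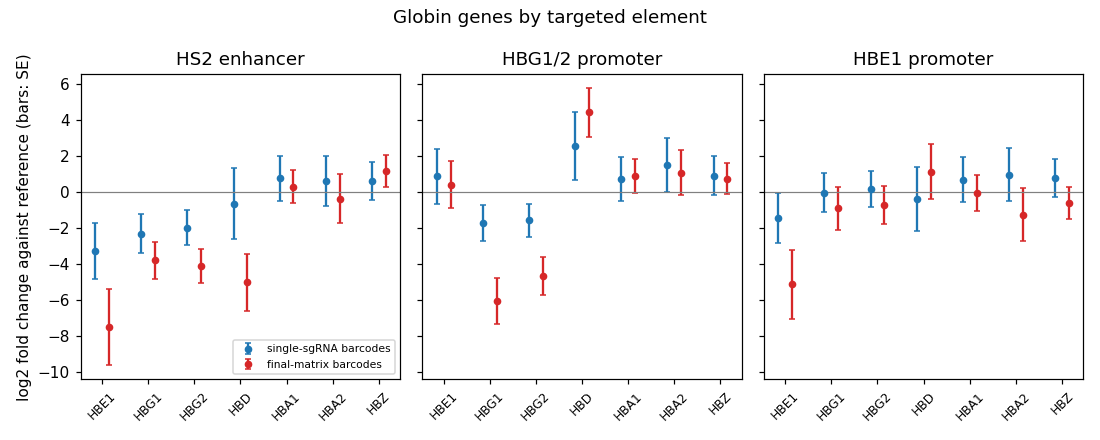
Log2 fold changes with standard errors of HBE1, HBG1, HBG2, HBD, HBA1, HBA2 and HBZ for each targeted element, in single-sgRNA barcodes against sgRNA63 (blue) and in final-matrix barcodes against the pooled HSBP1 sgRNAs (red). HBG1 with HBG1/2 promoter sgRNAs is at −1.73 in the former and −6.06 in the latter.

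Of the gene lists, the G1/S genes, which replicate DNA or prepare for it, stood apart. Their log2 fold changes averaged −1.47, −1.27 and −1.36 for HS2, the HBG1/2 promoter and the HBE1 promoter, and lay below 0 for 18, 19 and 20 of 20 genes. Camera gave adjusted p of 0.000760, 0.00108 and 0.000571, but adjusted p = 0.986 with an estimated correlation, and fry gave 0.416. The 3 contrasts share sgRNA63, so they are not independent. No single member passed: HELLS, a chromatin remodeller, was at −3.88, CCNE1, a cyclin of the G1/S transition, at −3.70, and MCM6, a subunit of the replicative helicase, at −2.69 with HBE1 promoter sgRNAs.

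Adjusted p from camera did not pass for the other 12 lists, given here for HS2, the HBG1/2 promoter and the HBE1 promoter. The beta-globin genes had 0.183, 0.835 and 0.403, and the alpha-globin genes 0.183, 0.148 and 0.183. The erythroid transcription factors had 0.227, 0.0746 and 0.528, with LYL1 at −2.77, NFE2L2 at −1.91 and LMO2 at −2.33 for the HBG1/2 promoter. The erythroid membrane genes had 0.750, 0.183 and 0.487, with KEL at 4.22, PKLR, the red cell pyruvate kinase, at 2.60 and XK at 2.05. The G2/M genes had 0.403, 0.177 and 0.266, with AURKA, a mitotic kinase, at 4.13, TACC3 at 2.71 and NUSAP1 at 1.64 for the HBG1/2 promoter. Heme synthesis genes had 0.968 in all 3, with ALAS2, the erythroid enzyme of the first step, at −4.30, STEAP3 at −4.10 and ALAD at −4.56 for HS2. Genes flanking the beta-globin locus had 0.968 in all 3, with STIM1 at −4.09, TRIM5 at 3.43 and RRM1 at −0.019 for the HBE1 promoter. For the HBG1/2 promoter, STIM1, a calcium sensor, was at −4.48 and was the 1 gene of its list to pass in edgeR when adjusted over the list alone.

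Heat shock genes had 0.183, 0.403 and 0.203, with TRIB3 at −3.84, HSPA1A at −2.99 and HSPA1B at −2.63 for HS2. Interferon response genes had 0.968, 0.758 and 0.968, with BST2 at −1.93 and IFITM1 at −0.98 for the HBG1/2 promoter. Glycolysis genes had 0.968, 0.968 and 0.528, with HK2 at 3.85, PGK1 at −1.78 and SLC2A1, a glucose transporter, at 1.90 for the HBE1 promoter. Housekeeping genes had 0.423, 0.477 and 0.528, with HPRT1 at −4.15 and TUBB at −0.74 for HS2. Ribosomal protein genes had 0.728, 0.758 and 0.280, with RPL22L1 at −1.66, RPL32 at −0.92 and RPL7L1 at −0.82 for the HBE1 promoter. None of these genes passed over all genes in edgeR.

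In the final-matrix barcodes camera passed the beta-globin genes for HS2 (adjusted p = 8.28e-08), with 5 of 5 values below 0. It passed the G2/M genes upward for the 3 elements (1.11e-05, 1.78e-05 and 0.00513), the G1/S genes downward for the HBG1/2 and HBE1 promoters (3.44e-06 and 0.00543), and the ribosomal protein genes for the HBE1 promoter (0.0404). With an estimated correlation the adjusted p was 0.0670 for the beta-globin genes, 0.440 or more for the cell cycle lists and 0.809 for the ribosomal protein genes, so none held.

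Markers of other cell types held low shares of the counts. Megakaryocyte genes, a lineage K562 cells can approach, held 0.00654% ± 0.00370 of the counts (SD, n = 8 batches), and leukocyte and fibroblast markers 0.0132% ± 0.00529. The mitochondrially encoded genes could not be tested, since 0 of 15 are in the files.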

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

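The tests of RNA from other cells, of reads shared between HBG1 and HBG2, of a few barcodes with many counts, of genes taking most of the counts and of HBE1 reads counted in HBD, and that of depth between the final-matrix barcodes and the rest, were chosen only after the result was seen, while the test of depth within the final-matrix barcodes was chosen before it.

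In edgeR, 8 direct tests between the targeted elements passed for globin genes when adjusted over the 3 pairs for each gene. None of the 8 passed over all genes or with at least 5 barcodes per pseudobulk, and several were lost without batch 8. None was refitted with thinned barcodes or without the barcodes with most counts. Between the HBG1/2 promoter and the HBE1 promoter, HBG2 differed by −1.74, HBG1 by −1.67, HBE1 by 2.30 and HBD by 2.93 on the log2 scale. Between HS2 and the HBE1 promoter, HBG2 differed by −2.14 and HBG1 by −2.26. Between HS2 and the HBG1/2 promoter, HBE1 differed by −4.15 and HBD by −3.18.

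The first pattern is that HBG1 and HBG2 were lower with HBG1/2 promoter sgRNAs, by more in the final-matrix barcodes than in the rest. Thinning keeps each barcode's expected share of HBG1 and HBG2, so it could show only whether sampling fewer counts changes these log2 values. Other properties that go with depth were not tested by it and stay open. With every final-matrix barcode thinned to 38000 counts, the log2 difference from the HSBP1 sgRNAs was still −4.31. Its two-sided exact permutation p over unpaired batch values was 0.00544. Sampling fewer counts was not the whole of the difference from the rest either. Thinned to 4838 counts, the median of the single-sgRNA barcodes outside the final matrix, the final-matrix barcodes had a ratio to HBE1 promoter and HSBP1 sgRNAs of −4.01 (SD 2.21, n = 8 batches). Its difference from the ratio outside was −2.95 (SD 2.03, below 0 in 7 of 8 batches, two-sided exact p = 0.0156). The thinned ratio rests on 26 counts of HBG1 and HBG2 with HBG1/2 promoter sgRNAs and 188 with the others. In all single-sgRNA barcodes thinned to 1000 counts, which gives the many shallow barcodes more weight, HBG1 was at −0.39 and HBG2 at −0.61. Reads shared between both genes stay open: their sum was lower (exact permutation p = 0.00233), but it would also be lower if 1 gene alone fell and its reads had been counted in both, so which of them fell is not settled. RNA from other cells in the shallow barcodes stays open and may account for the smaller difference there: outside the final matrix the ratio to HBE1 promoter and HSBP1 sgRNAs was −1.06 (SD 1.22, lower in 6 of 8 batches, exact p = 0.0469), against −5.41 (SD 2.31, lower in 8 of 8) inside it. Errors of sgRNA assignment outside it, where the median was 2 sgRNA reads against 39 inside, stay open as well. They were not tested, and this comparison cannot tell them from RNA of other cells. Repression by the sgRNAs at their target, which the design names, stays open as a hypothesis for the difference itself.

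The second pattern is that HBD was higher with HBG1/2 promoter sgRNAs in the final-matrix barcodes, over 100 CPM in 13 of 21. The 2 barcodes with most HBD counts held 47.0% of them, so these alone did not make the pattern. HBG1 and HBG2 took 0.271% of the counts with HSBP1 sgRNAs, too little for their loss to raise HBD's share. HBE1 reads counted in HBD were argued against by 9 barcodes with at least 10 HBD counts and more HBD than HBE1. An effect of the targeted promoter on HBD may remain, but the exact test of batch values did not pass after adjustment (0.0653).

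Single batches stood far from the others of their group in 9 of 50 groups tested. The rate of 1 in 20 by chance holds only for independent, normally distributed values. Many of these CPM values lie near 0 and groups share barcodes, so no excess over chance is shown. The gap to the nearest batch, as a share of the group's range, was 0.830 for HBD with HS2 sgRNAs in single-sgRNA barcodes, where batch 5 was at 318.7 CPM and the next at 55.7. It was 0.738 for HBE1 with HBE1 promoter sgRNAs, where batch 4 was at 771 CPM and the next at 231, and 0.640 for the alpha-globin locus with the same sgRNAs, where batch 5 was at 2030 CPM and the next at 899.6. With HSBP1 sgRNAs the gap for HBD was 0.960, from batch 4 at 163 CPM. In final-matrix barcodes the gap was 1 for HBD with HS2 sgRNAs, where batch 8 alone held a count. It was 0.576 for HBD with HBG1/2 promoter sgRNAs, where batch 3 was at 0 and the next at 399 CPM, and 0.527 for the alpha-globin locus with the same sgRNAs, where batch 2 was at 2856 CPM. With HSBP1 sgRNAs it was 0.859 for HBD and 0.714 for HSBP1, both from batch 4, at 200 and 654 CPM.

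The lentiviral construct, kept out of the gene counts, gave a signal where no sgRNA was listed: 241 of 481 such barcodes (50.1%) held 720 of its counts, against 339 of 339 barcodes with exactly one sgRNA. Where barcodes with no sgRNA serve as the reference, that reference may therefore include infected cells.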

How the results depend on the processing

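The alternatives of the final-matrix barcodes, of the pooled HSBP1 sgRNAs, of barcodes with at least 20000 counts, of edgeR's newer method, of dispersions without the robust option, of sgRNA63 as the only HSBP1 sgRNA among other elements, and of a pseudocount of 1 CPM were chosen after seeing the data; the others had been set in advance. Values are log2 with the p adjusted over the list or family in parentheses, and the cause was not tested for any change below. Direction and side of the threshold held in 262 of 381 alternative values for beta-globin genes, where 50 changed direction and 69 newly passed. They held in 138 of 159 for alpha-globin genes, where 21 changed direction, and in 154 of 165 in the final-matrix version, where 6 changed direction, 3 newly passed and 2 no longer passed. They held in 88 of 117 list tests, where 21 changed direction, 4 newly passed and 4 no longer passed, and in 12 of 12 exact tests. HBG1 and HBG2 of HS2 and of the HBG1/2 promoter kept their calls in every alternative run on the final-matrix version. The limit on barcodes of at least 1000 counts removed none, so it is no test, but the counts of values that held include it. They also include settings of the HBG1+HBG2 sum with too few batches for the exact sign-flip test to pass. There the side of the threshold could not change. The exact tests were varied only by the pseudocount. The final matrix with at least 3 single-sgRNA barcodes per pseudobulk leaves no sgRNA63 pseudobulk and gave no value.

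DESeq2, run without its filters for outlier counts and low means, called 310 genes for HS2, 234 for the HBG1/2 promoter and 246 for the HBE1 promoter. For the sgRNAs it called 230, 402, 197, 292, 339 and 221 (sgRNA44, 46, 56, 57, 80 and 82). HS2 then passed for HBE1 at −3.23 (0.00764), HBG2 at −2.05 (0.00764) and HBG1 at −2.31 (0.00764). In the final-matrix version HBE1 of its own promoter passed at −5.07 (0.0152).

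A total of at least 10 counts per gene gave 2 genes for HS2. Pseudobulks from 1 barcode up gave 1 for HS2 and 0 for the HBE1 promoter. HBA2 then turned to −0.022 for HS2 and HBG1 to 0.57 for the HBE1 promoter. On the HBG1+HBG2 sum this minimum gave −1.94 (0.0469) for the HBG1/2 promoter and 1.11 (0.0469) for the HBE1 promoter.

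Leaving the batch term out gave 168, 78 and 73 genes for HS2, the HBG1/2 promoter and the HBE1 promoter. HS2 passed for HBE1 at −3.91 (0.00197), HBG2 at −2.07 (0.0255) and HBG1 at −2.30 (0.0255). HBE1 turned to −0.087 for the HBG1/2 promoter and HBG1 to 0.067 for the HBE1 promoter. In the final-matrix version HBA2 turned to 0.18 for HS2, and HBD to −0.60 and HBA1 to 0.031 for the HBE1 promoter. List directions turned for flanking genes (0.982), glycolysis (0.992) and ribosomal protein genes (0.429) with HS2. They also turned for heme synthesis (0.966) with the HBG1/2 promoter, and for erythroid factors (0.982) and ribosomal protein genes (0.809) with the HBE1 promoter.

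Barcodes with no sgRNA as reference gave 6 genes for HS2 and 0 for the HBE1 promoter. HBE1 passed for HS2 at −3.90 (0.00137), with HBG2 at −1.56 (0.0384), HBG1 at −1.97 (0.0303) and HBD at −2.45 (0.0400), and for its own promoter at −2.28 (0.0325). HBG1 turned to 0.25 for the HBE1 promoter. HBBP1 turned to −1.39 for HS2, −0.31 for the HBG1/2 promoter and −2.20 for the HBE1 promoter. HBZ turned to −0.54, −0.19 and −0.36 in that order, HBA2 to −0.99, −0.16 and −0.72, and HBA1 to −0.18, −0.23 and −0.31. The HBG1+HBG2 sum passed at −1.75 (0.0117) for the HBG1/2 promoter, 1.20 (0.0117) for the HBE1 promoter, −1.73 (0.0234) for sgRNA56 and 1.26 (0.0234) for sgRNA82.

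Library size alone gave 0 genes for the HBE1 promoter. HBD turned to 0.26 for HS2, and HBG1 to 0.18 and HBD to 0.13 for the HBE1 promoter. Among differences, HBG2 turned to −0.15 for sgRNA44 minus sgRNA46 and 0.030 for HS2 minus the HBG1/2 promoter. HBD turned to 0.13 for HS2 minus the HBE1 promoter, and its call for HS2 minus the HBG1/2 promoter was lost at −2.59 (0.0538).

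With at least 5 barcodes per pseudobulk, 0 genes passed for the HBE1 promoter. HS2 turned to 3.06 for HBE1 and 3.26 for HBD. The HBE1 promoter turned to 5.30 for HBE1, 0.13 for HBG1 and 3.66 for HBD. HBE1 passed for the HBG1/2 promoter at 6.85 (0.0284), and sgRNA80 minus sgRNA82 turned to −1.07 for HBE1. Calls lost for the HBG1/2 promoter minus the HBE1 promoter were HBE1 at 1.56 (0.171), HBG1 at −1.38 (0.237), HBG2 at −1.43 (0.156) and HBD at 2.38 (0.109). For HS2 minus the HBG1/2 promoter, HBE1 at −3.79 (0.118) and HBD at −2.78 (0.277) were lost. For HS2 minus the HBE1 promoter, HBG1 at −3.05 (0.237) and HBG2 at −3.003 (0.156) were lost.

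All barcodes carrying the sgRNA gave 0 genes for the HBE1 promoter. HS2 passed for HBE1 at −3.80 (2.39e-05), HBG2 at −2.28 (2.86e-05), HBG1 at −2.29 (9.90e-05) and HBD at −2.26 (0.0116). The HBG1/2 promoter passed for HBG2 at −1.77 (0.00171) and HBG1 at −1.81 (0.00266). HBBP1 turned to −2.80, −0.72 and −3.73 for HS2, the HBG1/2 promoter and the HBE1 promoter. HBE1 turned to −0.18 for the HBG1/2 promoter, and the HBE1 promoter to −0.22 for HBG2, −0.039 for HBZ and −0.018 for HBA2. The sum passed for HS2 at −2.30 (0.0117), the HBG1/2 promoter at −2.04 (0.0117), and sgRNA44, 46, 56 and 57 at −1.91, −2.85, −1.98 and −1.92 (each 0.0234). It turned to −0.070 for the HBE1 promoter and −1.02 for sgRNA80. HBE1 turned to −1.37 for sgRNA80 minus sgRNA82 and HBG2 to 0.041 for sgRNA56 minus sgRNA57. HBE1 of HS2 minus the HBE1 promoter passed at −1.86 (0.0056). In the final-matrix version HBA2 turned to 0.42 for HS2 and HBE1 to −0.047 for the HBG1/2 promoter. There HBD of the HBG1/2 promoter was lost at 2.70 (0.0566), and HBE1 of its own promoter passed at −4.24 (0.0181).

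Thinning each barcode to 1000 counts gave 0 genes for the HBE1 promoter and turned HBE1 to −0.31 for the HBG1/2 promoter and HBG1 to 0.83 for the HBE1 promoter. HBG1 and HBG2 shrank to −0.39 and −0.61 for the HBG1/2 promoter and to −0.083 and −0.71 for HS2. Without the 5% of barcodes with most counts, 0 genes passed for the HBE1 promoter. HBD then turned to 0.14 for HS2, HBE1 to 0.96 and HBG1 to 0.82 for the HBE1 promoter, and the sum to −0.76 for sgRNA80. The sum for the HBG1/2 promoter shrank from −2.62 to −1.13 (0.375), and HBG1 and HBG2 to −0.045 and −0.66 there and to −0.81 and −0.91 for HS2, so the size of these values depends on the barcodes with most counts. Differences between elements were not refitted with thinned barcodes or without the barcodes with most counts.

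The newer quasi-likelihood method of edgeR gave 0 genes for the HBE1 promoter. HS2 passed for HBE1 at −3.94 (0.00654), HBG2 at −2.24 (0.00662) and HBG1 at −2.60 (0.00654). The HBG1/2 promoter passed for HBG2 at −1.61 (0.0428), HBG1 at −1.87 (0.0428) and HBD at 2.84 (0.0428), and HBD turned to 0.024 for the HBE1 promoter.

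Barcodes with sgRNAs of other elements as reference passed HBE1 for HS2 at −2.72 (0.0403) and for the HBG1/2 promoter at 2.81 (0.0124), with HBD at 4.02 (0.0124) for the latter. HBBP1 turned to −0.016 and HBA2 to −0.094 for HS2. For the HBE1 promoter HBG1 turned to 1.76, HBBP1 to −0.69 and HBD to 0.10. The sum passed at −2.19 (0.0117) for the HBG1/2 promoter and 2.41 (0.0117) for the HBE1 promoter. It also passed for sgRNA56 at −2.16 (0.0312), sgRNA80 at 1.44 (0.0234) and sgRNA82 at 2.48 (0.0234). With sgRNA63 as the only HSBP1 sgRNA in that reference, 0 genes passed for the HBE1 promoter, 1 for sgRNA44, 24 for sgRNA56 and 18 for sgRNA82. HBE1 passed at −3.06 (0.00966) for HS2 and 2.75 (0.00209) for the HBG1/2 promoter, HBD at 2.95 (0.00204) for the HBG1/2 promoter, and HBG2 at 1.59 (0.0147) for the HBE1 promoter. HBZ turned to −0.069 and HBA2 to −0.37 for HS2, and HBG1 to 1.56, which passed (0.0259), and HBBP1 to −0.65 for the HBE1 promoter. The sum passed at −2.18 (0.0117) and 2.52 (0.0117) for the HBG1/2 and HBE1 promoters. For sgRNA56, sgRNA80 and sgRNA82 it passed at −2.15 (0.0312), 1.56 (0.0234) and 2.59 (0.0234).

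The pooled HSBP1 reference gave 0 genes for the HBE1 promoter. HS2 turned to 0.21 for HBD and −0.82 for HBA2, and the HBE1 promoter to 0.26 for HBG1, 0.44 for HBD and −0.60 for HBA2. Single-sgRNA barcodes with at least 20000 counts also gave 0 genes for the HBE1 promoter. There HS2 passed for HBE1 at −4.90 (0.0187), HBG2 at −4.61 (0.000156), HBG1 at −4.50 (0.000618) and HBD at −4.90 (0.0187), and the HBG1/2 promoter for HBG2 at −3.39 (0.00642), HBG1 at −5.27 (0.00259) and HBD at 5.03 (0.0333). HBBP1 turned to −4.04, −0.63 and −1.76, and HBD to 1.45 for the HBE1 promoter.

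The final-matrix version gave 0 genes for the HBE1 promoter and 1 for sgRNA56. HS2 passed for HBE1 at −7.53 (0.00269), HBG2 at −4.11 (0.000596), HBG1 at −3.81 (0.00165) and HBD at −5.02 (0.00426), and the HBG1/2 promoter for HBG2 at −4.69 (0.000239), HBG1 at −6.06 (0.000194) and HBD at 4.43 (0.00423). HBBP1 turned to −3.88 and HBA2 to −0.37 for HS2. For the HBE1 promoter HBG2 turned to −0.73, HBBP1 to −1.998, HBD to 1.13, HBZ to −0.60, HBA2 to −1.27 and HBA1 to −0.065. For sgRNA44 minus sgRNA46, HBE1 turned to −0.30, HBG1 to −0.76, HBG2 to −0.80 and HBD to −1.45. For sgRNA56 minus sgRNA57, HBE1 turned to −0.13 and HBG1 to 2.85, and for sgRNA80 minus sgRNA82, HBE1 to −2.51 and HBD to −0.36. HS2 minus the HBG1/2 promoter turned to 2.25 for HBG1 and 0.58 for HBG2. HBD passed for HS2 minus the HBE1 promoter at −6.15 (0.00125) and was lost for the HBG1/2 promoter minus the HBE1 promoter at 3.30 (0.0606). For HS2 minus the HBG1/2 promoter HBD was at −9.45 and passed over all genes as well (0.0298), with only 1 HBD count with HS2 sgRNAs. In camera, lists newly passing there were beta-globin genes with HS2 (8.28e-08) and G2/M genes with the 3 elements (1.11e-05, 1.78e-05 and 0.00513). G1/S genes were lost with HS2 (0.0628) and still passed with the HBG1/2 and HBE1 promoters. With an estimated correlation none of these lists passed. Directions turned with HS2 for flanking genes (0.233), heme synthesis (0.566), interferon (0.481), glycolysis (0.746), housekeeping (0.338) and ribosomal protein genes (0.125). With the HBG1/2 promoter they turned for beta-globin genes (0.0552), heme synthesis (0.628) and glycolysis (0.916). With the HBE1 promoter they turned for beta-globin (0.471), alpha-globin (0.706), heat shock (0.915), interferon (0.256), housekeeping (0.481) and ribosomal protein genes (0.0404). The last passed at the preset correlation and not with an estimated one. Restricted to exactly one sgRNA, HBE1 of HS2 was lost at −5.54 (0.161) and HBA1 of the HBE1 promoter turned to 0.68.

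On the sum, final-matrix barcodes against other elements passed at −4.86 (0.0234) for the HBG1/2 promoter and −4.88 (0.0469) for sgRNA56. Against pooled HSBP1 sgRNAs sgRNA80 was at −2.25, from 1 barcode against 1 in 1 batch, which tests no change of direction. The mean over barcodes of log2(CPM + 1) turned to −0.17 for the HBE1 promoter, 0.14 for sgRNA46 and −1.01 for sgRNA80. With an estimated correlation the G1/S genes were lost with all 3 elements (0.986 each).

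Leaving out 1 batch at a time moved the number of genes between 0 and 2 for HS2, 0 and 1 for the HBE1 promoter, and 0 and 1 for sgRNA56 minus sgRNA57. For HS2 the ranges were −4.73 to 1.43 for HBE1, −3.05 to −1.11 for HBG2, −2.78 to −1.74 for HBG1, −1.31 to 1.83 for HBBP1 and −1.92 to 3.82 for HBD. HBE1 ran from −0.49 to 5.52 for the HBG1/2 promoter. For the HBE1 promoter HBE1 ran from −2.13 to 2.74, HBG2 from −0.11 to 0.89, HBG1 from −0.44 to 0.44 and HBD from −1.23 to 3.80. The sum for sgRNA80 ran from −0.28 to 0.57. In the final-matrix version HS2 ran from −9.49 to −3.69 for HBE1, −6.36 to −4.01 for HBD and −0.023 to 0.75 for HBA1. There the HBG1/2 promoter ran from −0.28 to 1.88 for HBE1, −0.036 to 3.06 for HBBP1 and −0.088 to 1.72 for HBZ. The HBE1 promoter there ran from −6.19 to −2.52 for HBE1, −0.55 to 2.60 for HBD and −0.43 to 0.49 for HBA1. HBE1 ran from −0.083 to 2.38 for sgRNA56 minus sgRNA57 and −0.12 to 0.35 for sgRNA80 minus sgRNA82, and HBG2 from −0.097 to 2.07 for sgRNA44 minus sgRNA46. Against the HBE1 promoter, HS2 ran from −2.80 to −1.31 for HBE1, −2.48 to −2.01 for HBG1, −3.01 to −1.82 for HBG2 and −0.93 to 0.24 for HBD. Against it the HBG1/2 promoter ran from 1.64 to 2.78 for HBE1, −1.82 to −1.51 for HBG1 and −1.85 to −1.59 for HBG2.

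With the same layout, the simulation called between 98% and 100% of changed genes at a dispersion of 0.1 and 2% of the genes lowered by 4 on the log2 scale at the dispersion estimated from the data. These genes were drawn only from those above a set CPM level. For such genes the spread between pseudobulks limits the calls, and a count of 0 does not show that few genes differ. Genes with lower counts were not tested in this way. Depth was not varied in the simulation.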

Other observations

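Among the tests reported here, those of the shared reference for the G1/S genes and the counts over other splits of the pseudobulk labels were chosen only after the result was seen.

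The single-sgRNA barcodes outside the final matrix were shallow, with a median of 4838 counts, and barcodes with no sgRNA listed had a median of 3490. Ribosomal protein genes held 3.87% ± 0.858 of the counts per batch (SD, n = 8 batches), heme synthesis and iron supply genes 0.949% ± 0.201 and housekeeping genes 1.33% ± 0.196. Beta-globin genes held 0.166% ± 0.131 and alpha-globin genes 0.0636% ± 0.0336.

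The third pattern is that the G1/S genes were lower with each of the 3 elements against sgRNA63, which camera called at the preset correlation only. With an estimated correlation in camera the list passed with no element (adjusted p = 0.986 each), nor did it pass in fry, and no single member passed. If a property of the few sgRNA63 barcodes caused the pattern, these genes should not be lower against another reference. The tables disagree on this. In the edgeR fit against barcodes with no sgRNA their mean log2 fold changes were −1.08 for HS2, −0.82 for the HBG1/2 promoter and −0.95 for the HBE1 promoter, below 0 for 18, 16 and 19 of 20 genes. The summed share of counts in these genes, taken within batches against the same barcodes, was not detectably lower, at a log2 ratio of −0.13 (SD 0.51, n = 8 batches) for HS2, 0.104 (SD 0.26) for the HBG1/2 promoter and −0.041 (SD 0.41) for the HBE1 promoter (two-sided exact p of 0.516, 0.289 and 0.773, each 0.773 adjusted). With sgRNA63 that share was higher than with no sgRNA in 4 of 4 batches (0.58, SD 0.36, exact p = 0.125, the smallest that 4 batches allow). In the fit against barcodes with no sgRNA, the alpha-globin genes HBZ, HBA1 and HBA2 also lay below 0 for each of the 3 elements. The share of all genes below 0 was not taken there, and no list test was run against that reference. That fit thus does not show a fall particular to the G1/S genes. A property of the sgRNA63 barcodes and an effect common to the 3 elements therefore both stay open.

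For the number of genes past the threshold in edgeR, the pseudobulk labels were redrawn within batches to give 21 splits, the real one included, with the dispersions of the real fit kept. Chance could not be excluded for the HBE1 promoter (real count 1, reached in 10 of 21 splits, highest other 149). Over the 12 contrasts of the single-sgRNA fit together, 13 of 21 splits gave a gene, so this fit often called genes with redrawn labels. The differences between elements in this fit and the calls of DESeq2 were not put to this test. The split with 149 genes gave 149 as well with dispersions estimated for its own labels, so the dispersions kept did not make it. It may reflect a structure of the samples, such as their depth, which was not tested. Where the real count was 0, all 21 splits reach it by construction and nothing follows about chance. This holds for HS2 (highest other 10), the HBG1/2 promoter (highest other 6), sgRNA44 (highest other 1), sgRNA46, sgRNA56, sgRNA57, sgRNA80 and sgRNA82, and the 3 pairs of sgRNAs of an element (highest other 0). In the final-matrix barcodes it holds for the 3 elements and for sgRNA44, sgRNA46, sgRNA80 and sgRNA82 (highest other 0). There sgRNA57, with 2 pseudobulks, had a real count of 0 and 1 gene in 1 other split. For sgRNA56 the real count of 1, which is HBG2, was reached in 1 of 21 splits, the real one, with 0 as the highest other. Over the 9 contrasts of that version together, 2 of 21 splits gave a gene, so chance could not be excluded.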
